A study of Mus musculus with 13 samples.

How the data were processed

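RNA-seq values of sorted mouse splenic CD4 T cells were analysed in 13 libraries of 3 populations. Regulatory T cells (here Treg) were CD4+ cells that carried the Foxp3 GFP reporter and no surface PD-1. The PD1hi population was high for surface PD-1 and negative for the reporter, and conventional T cells (here Tconv) were negative for both. The sample titles name experiments 3, 5 and 6, each with all 3 populations, and call 4 libraries a replicate of another library of the same experiment and population. The labels do not say whether such a pair is another animal or a second library of the same RNA, so p-values measure the spread between these samples, which may in part be technical.

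Per the labels' protocols, RNA was extracted with Trizol, ribosomal RNA was depleted with a low-input RiboMinus kit, and libraries were made with the Ion Total RNA-seq kit for Ion Torrent sequencing. Per the submitters' processing notes, Picard, HTSeq 0.5.4 and limma were used, and the builds hg19, GRCh37 and mm9 are named. The aligner, the role of each build and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of 18649 genes by 13 libraries in the unit signal, with Ensembl gene IDs and symbols and a line of column names. Its file name calls the values counts scaled by size factors. Every deposited signal value equalled 1 plus a whole number of reads times a constant of its library, within 0.001 reads, so an added value of 1 was subtracted to give the scaled count. The library constants gave depths of 15971126 to 24216463 reads in genes, which were used for depth, read counts, folds of genes with 0 to 3 reads in a population and sampling noise and for no test of differences between populations.

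Libraries of the same experiment and population were averaged, which gave 9 values, 3 per population. A chi-square comparison of reads was made first over genes with at least 10 reads in a pair. Pairs titled replicate differed by 7.768, 8.693, 9.047 and 73.5 times sampling noise (chi-square per degree of freedom), so every pair differed by more than sampling noise. The last value belongs to the Treg pair of experiment 3, and pairs from different experiments gave 15.43 to 92.73. Genes with a mean scaled count of at least 10 over the 9 values were tested, which left 14177. The test was limma 3.58.1 in R 4.3.3, with a trend on mean level, on log2(scaled count + 1), 2-sided, with 1 variance estimate for all 3 populations and Benjamini-Hochberg adjusted p under 0.05. Fold changes are therefore on the log2(scaled count + 1) scale, which understates the change of low genes, and are given with their standard error (SE). Where a population held no read of a gene, the fold was computed against a floor of 3 reads over the population. Where it held 1 to 3 reads, the ratio of reads per summed size factor, both summed over all libraries of a population, is given with an exact 95% counting interval. The fold against the floor was scaled in the same way, so neither is the ratio of the printed means. Such floors and intervals cover counting error only, since PCR reads are not independent molecules.

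Before the data were examined, 25 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists cover Treg identity, effector Treg, follicular helper, inhibitory receptors and exhaustion, anergy, naive and quiescence, effector and memory activation, Th1, Th2, Th17, T cell cytokines, type 1 regulatory (Tr1), cytotoxic, chemokine receptors, cell cycle, glycolysis, type I interferon response, immediate early and stress, apoptosis regulators and pan T cell genes. Another 5 hold markers of other cell types: B cells, plasma cells, myeloid and dendritic cells, CD8 T with NK and innate-like T cells, and erythroid cells with platelets. The lists share members, so calls of overlapping lists are not separate results. For example, Nrp1, Nt5e and Folr4 are in the Treg identity and anergy lists, and Ccr4, Ccr8 and Il10 in effector Treg and Th2. Il10, Lag3, Prdm1, Irf4 and Batf are in effector Treg and Tr1, and Tox in follicular helper and inhibitory receptors. Lists with at least 3 tested genes were tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 75 tests. Limma's fry, which tests the members of a list without reference to the other genes, was run beside it, also adjusted over the 75 tests. List calls are those of camera unless fry is named. Camera was repeated with the correlation estimated from the data. Its adjusted p rose then also where the estimate lay below 0.01. For T cell cytokines in PD1hi against Tconv the estimate was 0.00847, and the adjusted p was 0.0323 instead of 2.69e-05. A call lost with the estimated correlation therefore does not by itself show that members of the list covaried. The estimates ran from -0.0367 for pan T cell genes to 0.431 for myeloid and dendritic genes. They were 0.417 for cell cycle, 0.324 for B cell, 0.298 for follicular helper and 0.265 for Th1 genes. Members of those lists did covary, so their p-values at the preset correlation are too small. By the naming rule, each comparison names Cd4, Foxp3 and Pdcd1, and the 8 genes with the largest changes per direction. These had a mean of at least 50 in the higher population and the same direction in all 3 experiments, and predicted genes and receptor segments were left out. The rule adds up to 4 members with the smallest adjusted p from each list past its test and members that moved against it. From other lists it adds up to 2 members past the gene test. Markers of other cell types may be named as levels.

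The experiment numbers were taken to pair the values, since the titles give each number to 1 experiment that holds all 3 populations. The main fit nonetheless held no term for the experiment, so its SEs and p-values are unpaired. The paired fit, with the experiment as a block, was an alternative. In a check of the pairing, deviations from the population means correlated across genes at 0.143 on average within an experiment (range -0.07 to 0.298, over 0.1 in 6 of 9 pairs). Between experiments the mean was -0.072, and 8 of 9 values correlated best with their own experiment. Deviations of a population cancel over its 3 values, so the value between experiments largely follows from that within them. It and the count of 8 of 9 are therefore not separate evidence. The comparison of PD1hi and Treg changes against the same Tconv values was set beside 100 simulations with unchanged groups, the overlap of independent lists and a split of the Tconv values. In a test on simulated data with 200 changed genes in PD1hi, the procedure ran on 14136 genes. In PD1hi against Tconv it recovered 53.1% of the genes changed 2-fold and 80.6% of those changed 4-fold, with 12.1% of its calls false. With no changed gene it called 0 genes in each of the 3 comparisons.

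Alternatives were 2 other pseudocounts (0.5 and 5), no filter or a minimum mean of 50, TMM factors or equal totals as scaling, the experiment as a block, libraries as separate samples, duplicateCorrelation, only libraries not titled replicate, only the 2 groups compared, and each of the 9 values left out in turn. Chosen after the data were seen were runs without the second Treg library of experiment 3 or without that library and the PD1hi library of experiment 6, vooma precision weights, and duplicateCorrelation for the count of shared genes. Of the gene IDs, 17488 (93.8%) are in the GENCODE M21 annotation, which is of another build than mm9. It was used for names, transcript length, GC content and exon overlaps, and no coordinates are printed. Exons of 21 of the 170 named genes overlap an exon of another gene in the table on the opposite strand: Anxa2, Ccdc46, Ccr9, Cd160, Cd247, Chn1, Cxcr5, Dgka, Foxp3, Hif1a, Hopx, Il12rb2, Il21, Irf7, Maf, Ndrg1, Penk, Slc7a10, Tk1, Tnc and Tox. Ccr9, Cd247 and Foxp3 also overlap another gene on the same strand, which no strand setting resolves. With the strand setting not given, the values of all 21 are uncertain to that extent, and so are those of near-identical families such as the immunoglobulin, MHC class II, Ifit, Oas, Gbp, Klr, S100 and granzyme genes. The values of 5 further genes are not reported here, while their lists kept them as members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.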

Results

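The libraries compare splenic CD4 T cells that are high for the inhibitory receptor PD-1 and lack Foxp3 (PD1hi, 3 libraries) with Foxp3+ regulatory T cells (Treg, 5 libraries) and with conventional cells that lack both (Tconv, 5 libraries). Each library held between 15971126 and 24216463 reads in genes. The PD1hi library of experiment 6 was the shallowest and the second Treg library of experiment 3 the deepest. Levels are scaled counts, given as the mean ± SD of 3 values per population (n = 3), 1 per experiment, and fold changes are log2 values ± SE from limma.

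The genes behind the sort were measured first. Pdcd1 (ENSMUSG00000026285), which encodes PD-1, was at 37370 ± 3290 in PD1hi, 1955 ± 38.5 in Treg and 1132 ± 136 in Tconv. Foxp3 (ENSMUSG00000039521), the lineage factor of Treg, was at 15890 ± 513 in Treg, 291.5 ± 35.8 in Tconv and 106 ± 33.4 in PD1hi. Cd4 (ENSMUSG00000023274) was at 40740 ± 5840 in PD1hi, 28070 ± 1640 in Tconv and 17160 ± 1940 in Treg. The first principal component (37.1% of variance) parted PD1hi from Tconv and the second (26.4%) parted Treg from the others. On the third (7.88%), the PD1hi library of experiment 6 and the second Treg library of experiment 3 scored -53.35 and -50.67, while the other Treg libraries scored 6.3 to 16.53 and the other PD1hi libraries 31.63 and 35.41.

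**Figure D1:**
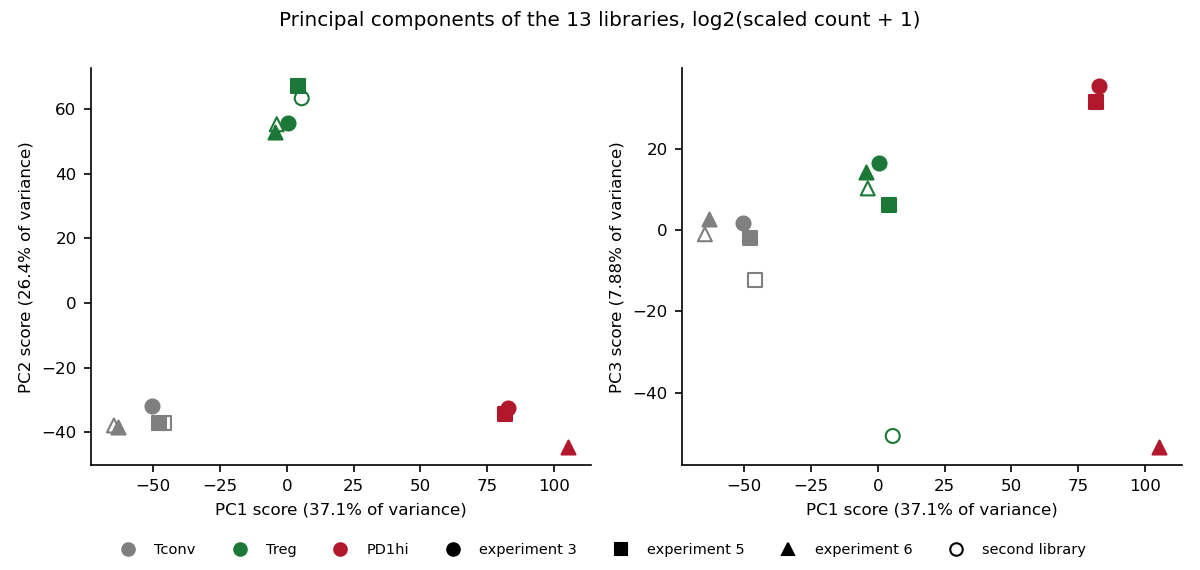
Principal component scores of the 13 libraries, PC1 against PC2 on the left and PC1 against PC3 on the right; colour gives the population, marker shape the experiment, and open markers the libraries titled replicate. The populations separate on PC1 and PC2, and 2 libraries lie below -50 on PC3.

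The first question was how PD1hi cells differ from Tconv. Follicular helper genes rose: Sostdc1, a secreted inhibitor of Wnt and BMP signals, by 7.43 ± 0.21 (22680 ± 2270 against 134.2 ± 40.5), the B cell follicle homing receptor Cxcr5 by 3.54 ± 0.15, the transcriptional coactivator Pou2af1 by 3.2 ± 0.17 and Tbc1d4, a regulator of vesicle traffic, by 3.08 ± 0.17. Genes of naive cells fell: the chromatin organiser Satb1 fell by 4.57 ± 0.14, the lymph node homing receptor Ccr7 fell by 3.28 ± 0.13 and Actn1, an actin crosslinker, fell by 3.23 ± 0.15. The cytokine gene Il21, whose product acts on B cells, rose by 5.04 ± 0.36 to 3296 ± 683. Several Treg genes rose as well, among them the transcription factor Ikzf2 by 4.04 ± 0.14 and the receptor Nrp1 by 3.07 ± 0.15, while Foxp3 fell by 1.5 ± 0.22 (adjusted p = 0.000356).

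Of the 22 follicular helper genes tested in PD1hi against Tconv, 21 rose and 1 was not past the test, also when adjusted over the list alone. The follicular helper list had adjusted p = 2.48e-23, and adjusted p = 0.0387 with an estimated correlation. Of 20 naive and quiescence genes, 17 fell, 2 were not past the test and 1 rose, Il6st, a shared subunit of cytokine receptors, by 0.77 ± 0.16; counts adjusted over the list alone were the same. The naive list had adjusted p = 2.96e-15, and adjusted p = 0.00425 with an estimated correlation. Of 24 Treg identity genes, 13 rose, 5 fell and 6 were not past the test, and 13 and 5 when adjusted over the list alone. The Treg identity list had adjusted p = 7.88e-05, and adjusted p = 0.0323 with an estimated correlation. The rises included the surface protein Cd83 (4.59 ± 0.21) and the inhibitory receptor Ctla4 (2.7 ± 0.14). The falls were Foxp3, the extracellular protein Ecm1 (-2.69 ± 0.14), Fgl2, a secreted suppressive protein (-1.35 ± 0.19), the IL-2 receptor chain Il2ra (-0.64 ± 0.13) and the integrin Itgae (-1.53 ± 0.23). Among 20 inhibitory receptor and exhaustion genes, 14 rose and 1 fell over all genes and adjusted over the list alone. The inhibitory list had adjusted p = 2.37e-07, and adjusted p = 0.0459 with an estimated correlation. Tigit, an inhibitory receptor, rose by 4.12 ± 0.21 to 10490 ± 1780, the nuclear factor Tox rose by 2.01 ± 0.16 and the AP-1 factor Batf by 1.82 ± 0.16, whereas Klrg1, a receptor of terminal effector cells, changed by -2.68 ± 0.68. Of 16 T cell cytokine genes, 10 rose and none fell, or 11 and 0 adjusted over the list alone. The T cell cytokine list had adjusted p = 2.69e-05, and adjusted p = 0.0323 with an estimated correlation. The cytokine genes that rose included Csf1, a growth factor of macrophages (4.08 ± 0.31), the regulatory cytokine Il10 (4.61 ± 0.61) and Tnfsf11, the ligand of RANK (3.27 ± 0.35).

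The other lists past the test in this comparison were not past it with an estimated correlation. Of 27 cell cycle genes, 21 rose, the same number adjusted over the list alone, with the proliferation marker Mki67 at 2.18 ± 0.17, the mitotic kinase Plk1 at 1.91 ± 0.22, the thymidine kinase Tk1 at 1.95 ± 0.24 and the thymidylate synthase Tyms at 1.49 ± 0.18. The cell cycle list had adjusted p = 1.49e-10, but adjusted p = 0.187 with an estimated correlation. Of 18 effector Treg genes, 11 rose and 3 fell, or 12 and 3 adjusted over the list alone, with the integrin Itgb8 at 5.6 ± 0.29, the costimulatory receptors Tnfrsf4 (3.01 ± 0.2) and Icos (1.68 ± 0.11) up, and Klrg1, the chemokine receptor Ccr4 (-1.18 ± 0.34) and the IL-33 receptor Il1rl1 (-2.21 ± 0.61) down. The effector Treg list had adjusted p = 1.02e-05, but adjusted p = 0.127 with an estimated correlation. Of 14 anergy genes, 8 rose and 3 fell, also when adjusted over the list alone. The anergy list had adjusted p = 0.00634, but adjusted p = 0.162 with an estimated correlation. The ecto-nucleotidase Nt5e (2.64 ± 0.23), the folate receptor family member Folr4 (2.2 ± 0.14) and the transcription factor Egr2 (2.5 ± 0.18) rose, while the diacylglycerol kinase Dgka (-0.97 ± 0.15), Ndrg1 (-1.27 ± 0.28) and the antiproliferative gene Tob1 (-1.02 ± 0.27) fell. Of 18 Tr1 genes, 8 rose and 2 fell, also adjusted over the list alone, with Maf (2.54 ± 0.16) and Irf4 (2.03 ± 0.18), both transcription factors, up and the adhesion molecules Cd226 (-1.84 ± 0.19) and Itga2 (-3.51 ± 0.37) down. The Tr1 list had adjusted p = 0.0259, but adjusted p = 0.273 with an estimated correlation. The Tr1 call was lost without the PD1hi value of experiment 5 (adjusted p = 0.13). Of 18 type I interferon response genes, 10 fell and 2 rose, or 11 and 3 adjusted over the list alone. The type I interferon response list had adjusted p = 0.00105, but adjusted p = 0.145 with an estimated correlation. The antiviral genes Ifit3 (-2.37 ± 0.21) and Ifit2 (-1.87 ± 0.29), the deconjugating enzyme Usp18 (-2.09 ± 0.18) and Irf7 (-1.04 ± 0.14) fell, and Oas1a (0.79 ± 0.15) and Mx1 (0.64 ± 0.21) rose.

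Of 9 Th17 genes tested, 4 fell and 1 rose, or 5 and 1 adjusted over the list alone. The Th17 list had adjusted p = 0.0205, but adjusted p = 0.244 with an estimated correlation, and 0.111 with a minimum mean of 50. The chemokine receptor Ccr6 was at -2.21 ± 0.35. Il17re and Il23r, cytokine receptors with 2 reads each in PD1hi, were higher in Tconv by 46.8-fold (95% counting interval 12.7 to 390) and 41.5-fold (11.3 to 346), and the IL-1 receptor Il1r1 was at 1.43 ± 0.49. Of 16 chemokine receptors, 6 fell and 4 rose, or 7 and 4 adjusted over the list alone. The chemokine receptor list had adjusted p = 0.0407, but adjusted p = 0.253 with an estimated correlation. Ccr9 (-3.17 ± 0.23) and Ccr2 (-2.86 ± 0.3) fell, and Cxcr4 (1.88 ± 0.45), Cxcr3 (0.61 ± 0.14) and Ccr8 (1.53 ± 0.28) rose with Cxcr5. The chemokine receptor call was also lost with the experiment as a block (0.0646), with a minimum mean of 50 (0.109) and without the PD1hi (0.0564), Treg (0.051) or Tconv (0.0532) value of experiment 3 or the Tconv value of experiment 5 (0.0913, all adjusted p). Some calls of single genes were lost when 1 of the 9 values was left out. The adjusted p was 0.0969 and 0.0583 for Ccr4 without Tconv of experiment 3 and 5, 0.0646 and 0.0518 for Il1rl1 without Tconv 5 and PD1hi 3, 0.0756 and 0.0608 for Tob1 without Tconv 3 and PD1hi 5, and 0.0667 and 0.0625 for Cd4 without PD1hi 5 and Tconv 5. Mx1 lost its call in 6 of 9 cases and Il1r1 in 8, with the highest adjusted p, 0.176 and 0.195, without Tconv 6. Other alternatives ended calls too: Il1r1 lost it with the experiment as a block (limma adjusted p = 0.0577) and Cd4 with duplicateCorrelation (0.092). Ccr4 (0.0642) and Il1rl1 (0.0545) lost theirs with only the 2 groups compared.

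Markers of other cell types also differed between PD1hi and Tconv. Of 16 B cell genes, 5 rose and none fell, also adjusted over the list alone. The B cell list had adjusted p = 0.0153, but adjusted p = 0.432 with an estimated correlation and 0.0685 without the Tconv value of experiment 6. The IgM heavy chain Ighm was at 36650 ± 2560 against 21760 ± 1500, the light chain Igkc at 10690 ± 4700 against 3672 ± 884, the B cell lectin Cd22 at 1675 ± 243 against 178.5 ± 51.8 and Faim3 at 28.03 ± 5.95 against 1.066 ± 1.07, whereas the B cell antigen receptor component Cd79a was at 42.15 ± 5.5 against 29.33 ± 4.29. The MHC class II gene H2-Aa was at 214.5 ± 86.2 against 279.5 ± 345, with 676.7 in the Tconv value of experiment 3. Of 6 plasma cell genes, 4 rose, or 6 adjusted over the list alone, with the joining chain Igj at 3866 ± 1350 against 1586 ± 406. The plasma cell list had adjusted p = 0.00223, but adjusted p = 0.133 with an estimated correlation. Its genes include Irf4, also a member of the Tr1 and effector Treg lists, so the rise is not of plasma cell markers alone. Of 8 CD8 T, NK and innate-like T cell genes, 2 fell, also adjusted over the list alone, with the NK receptor Klrb1c at 261.6 ± 92.5 against 984.1 ± 59 and the CD8 chain Cd8b1 at 98.11 ± 40.2 against 423.6 ± 37.7. The CD8 T list had adjusted p = 0.0113, but adjusted p = 0.172 with an estimated correlation.

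The remaining lists were not past the camera test in PD1hi against Tconv, although members of most of them changed. Of these lists, glycolysis (up, fry adjusted p = 0.00154), cytotoxic (down, 0.0281) and Th2 (up, 0.0484) were past fry. Effector and memory genes went both ways (11 up, 8 down of 25, adjusted over the list alone 12 and 8; adjusted p = 0.277), with Anxa2, a calcium-dependent membrane binding protein, at 1.94 ± 0.16 and S100a11, a calcium-binding protein, at 1.93 ± 0.16. Glycolysis genes did so too (7 up, 3 down of 17, adjusted over the list alone 8 and 4; adjusted p = 0.111), with the hypoxia factor Hif1a at 2.95 ± 0.15 and the glucose transporter Slc2a3 at -2.01 ± 0.15. Among Th1 genes 5 rose and 4 fell of 12 (also adjusted over the list alone; 0.968), among Th2 genes 4 and 2 of 9 (5 and 2; 0.296), and among cytotoxic genes 2 and 4 of 14 (2 and 5; 0.097). Immediate early and stress genes gave 3 up and 2 down of 17 (also adjusted over the list alone; 0.872), apoptosis regulators 6 and 6 of 18 (6 and 7; 0.948), and pan T cell genes 3 and 4 of 18 (also alone; 0.855), with the kinase Zap70 at 1.44 ± 0.18 and the adaptor Trat1 at -2.69 ± 0.17. Myeloid and dendritic genes gave 3 up and 1 down of 14 and erythroid and platelet genes 0 of 5, both also adjusted over the list alone (adjusted p = 0.93 and 0.501). The sign of the median, mean and test disagreed in 4 of the 25 lists (Th1, apoptosis regulators, pan T cell, and myeloid and dendritic), none of them past the test.

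**Figure D2:**
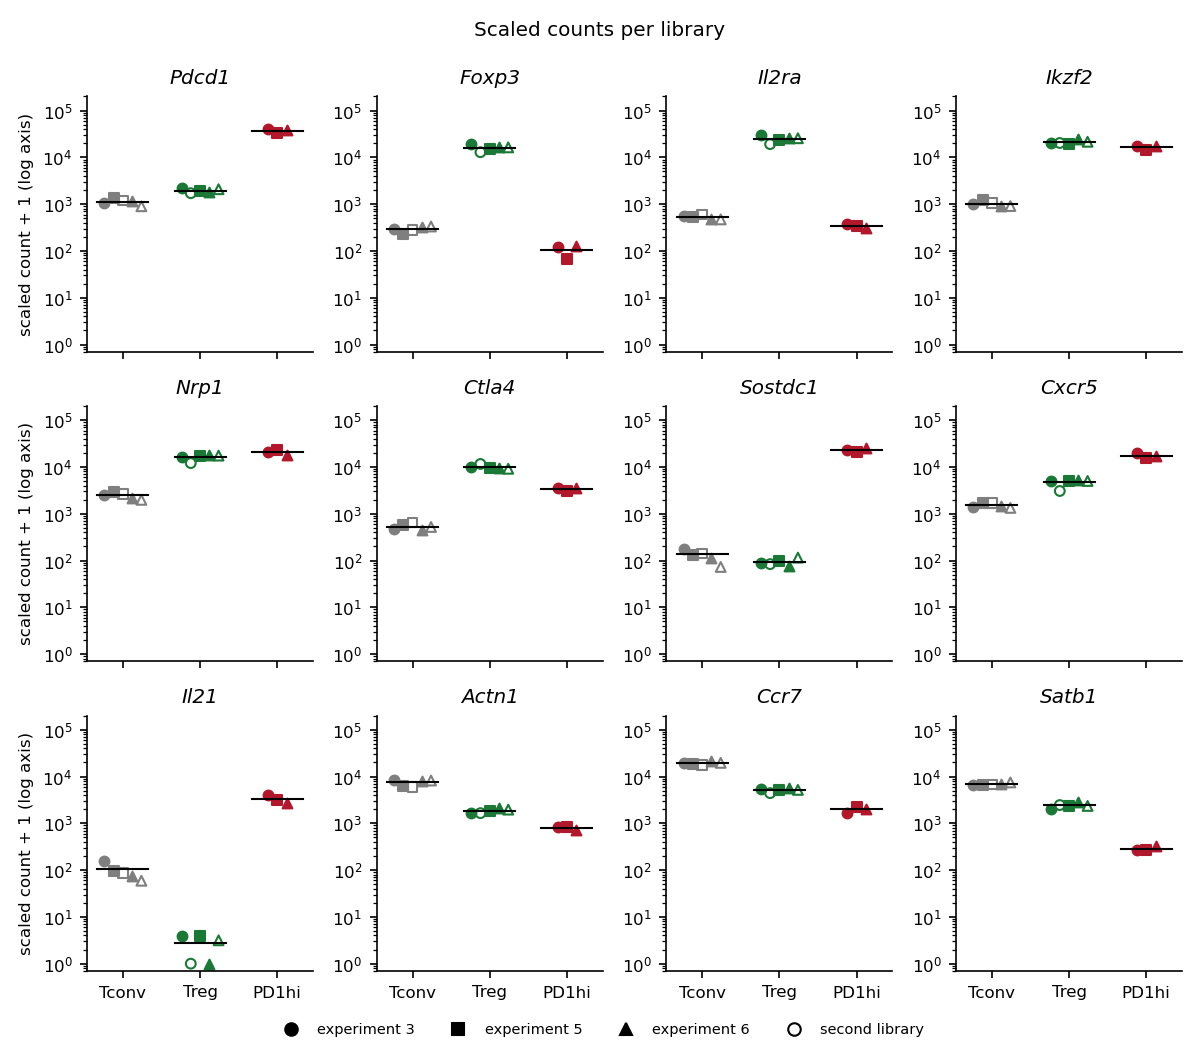
Scaled counts plus 1 of 12 named genes in each of the 13 libraries, on a log axis; marker shape gives the experiment, open markers the libraries titled replicate, and the black line the mean of the 3 values per population. Foxp3 and Il2ra were highest in Treg, Ikzf2 and Nrp1 were near their Treg level in PD1hi, and Satb1 was lowest in PD1hi.

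The largest rises in PD1hi over Tconv were led by genes with hardly a read in Tconv. The neuropeptide gene Gal had no read in Tconv and was at least 686-fold higher (422 ± 102). Tmem26 and the amino acid transporter Slc7a10 had 1 read in Tconv (982-fold, counting interval 175 to 38800, and 941-fold, 168 to 37200), and the keratin Krt17 had 3 (464-fold, 158 to 2260). The adhesion molecule Kirrel3 rose by 8 ± 0.81, Ccdc80 by 7.27 ± 0.43 and the matrix gene Fbn2 by 7.02 ± 0.64. Among the largest falls were the TGF-beta family receptor Acvrl1 (-7.82 ± 0.71), Igfbp4, which binds insulin-like growth factors (-6.29 ± 0.34), the surface antigen Ly6c1 (-6.05 ± 0.35), Pdlim4 (-6.03 ± 0.96) and the DNA polymerase Dntt (-6.02 ± 0.36). Adamts14, a protease with 1 read in PD1hi, was 215-fold higher in Tconv (38.4 to 8530), and Tspan9 and the protease Mmp25, with 2 reads each, were 122-fold (33.7 to 1010) and 112-fold higher (30.8 to 930). In all, 3700 of 14177 genes (26.1%) passed the limma test in this comparison, 2012 higher and 1688 lower in PD1hi, and 2320 of them differed by more than 2-fold. With libraries scaled to equal totals, 2450 were higher and 1298 lower (65.4% higher against 54.4%), and the median of all genes moved by 0.142. Of 25 lists, 15 passed with the preset correlation and 5 with an estimated one.

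The second comparison asked how PD1hi cells differ from Treg. The Treg markers fell in PD1hi: Foxp3 fell by 7.27 ± 0.22, Il2ra fell by 6.17 ± 0.13 (343.6 ± 31.3 against 24690 ± 994), Itgae fell by 7.96 ± 0.23 and Lrrc32, the surface anchor of latent TGF-beta, fell by 8.78 ± 0.34. The bone matrix protein and cytokine gene Spp1 rose by 10.28 ± 0.58 to 4236 ± 268, and Il21, with 8 reads in Treg, rose by 10.25 ± 0.36. Follicular helper genes were again higher, with Sostdc1 at 7.93 ± 0.21, Pou2af1 at 5.18 ± 0.17 and Tnfsf8, the ligand of CD30, at 4.23 ± 0.18. The naive cell factor Tcf7 was at 33790 ± 3350 in PD1hi against 5238 ± 338 in Treg, a rise of 2.69 ± 0.13.

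Of 24 Treg identity genes, 16 fell, 2 rose and 6 were not past the test, or 17 and 2 adjusted over the list alone. The Treg identity list had adjusted p = 4.95e-14, and adjusted p = 0.00425 with an estimated correlation. Ecm1 fell by 4.39 ± 0.14, while the opioid precursor Penk (0.9 ± 0.22) and the transcription factor Plagl1 (2.44 ± 0.69) were higher in PD1hi. Of 22 follicular helper genes, 20 rose and none fell, or 20 and 1 adjusted over the list alone. The follicular helper list had adjusted p = 5.18e-26, and adjusted p = 0.0323 with an estimated correlation. Of 20 naive and quiescence genes, 13 fell and 2 rose, also adjusted over the list alone. The naive list had adjusted p = 6.97e-07, and adjusted p = 0.0219 with an estimated correlation. Satb1 (-3.07 ± 0.14) and Ccr9 (-3.63 ± 0.23) fell, and Tcf7 and the TGF-beta coreceptor Tgfbr3 (1.32 ± 0.29) rose. Of 16 T cell cytokine genes, 8 rose and 2 fell, or 10 and 2 adjusted over the list alone. The T cell cytokine list had adjusted p = 4.04e-05, and adjusted p = 0.0323 with an estimated correlation. Il4, the cytokine of Th2 and follicular helper cells, rose by 6.4 ± 0.53, interferon gamma (Ifng) by 4.03 ± 0.36 and Tgfb3 by 3.71 ± 0.3, and lymphotoxin alpha (Lta, -0.92 ± 0.16) and the IL-27 and IL-35 subunit Ebi3 (-0.92 ± 0.28) fell.

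Further lists past the preset-correlation test lost it with an estimated correlation. Of 9 Th17 genes, 7 fell and 1 rose, or 8 and 1 adjusted over the list alone, with Ccr6 at -4.76 ± 0.35, the aryl hydrocarbon receptor Ahr at -2.49 ± 0.34 and Il1r1 at 1.92 ± 0.49. The Th17 list had adjusted p = 9.27e-05, but adjusted p = 0.0945 with an estimated correlation. Il23r was 36.7-fold higher in Treg (counting interval 9.96 to 306). Of 18 effector Treg genes, 9 fell and 2 rose, or 10 and 4 adjusted over the list alone, with Klrg1 at -5.33 ± 0.68, Ccr4 at -3.33 ± 0.34, the transcription factor Prdm1 at -2.25 ± 0.26 and the costimulatory receptor Tnfrsf9 at -1.82 ± 0.15, against Batf at 0.92 ± 0.16 and the inhibitory receptor Lag3 at 2.13 ± 0.49. The effector Treg list had adjusted p = 0.00788, but adjusted p = 0.268 with an estimated correlation. Of 18 type I interferon response genes, 9 fell and 2 rose, or 10 and 2 adjusted over the list alone, with Usp18 at -2.29 ± 0.18, Ifit3 at -1.91 ± 0.21 and Ifi44 at -2.16 ± 0.41, against Oasl2 at 0.9 ± 0.2 and Mx1 at 0.85 ± 0.21. The type I interferon response list had adjusted p = 0.000844, but adjusted p = 0.145 with an estimated correlation. Of 16 chemokine receptors, 8 fell and 4 rose, or 10 and 4 adjusted over the list alone, with Ccr2 at -4.12 ± 0.3 down and Cxcr5 (1.91 ± 0.15), Cxcr6 (1.74 ± 0.28), Cxcr4 (1.64 ± 0.45) and Cx3cr1 (2.31 ± 0.64) up. The chemokine receptor list had adjusted p = 0.012, but adjusted p = 0.182 with an estimated correlation.

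Of 12 Th1 genes, 7 rose and 3 fell, also adjusted over the list alone, with the chemokines Ccl3 (3.89 ± 0.46) and Ccl4 (3.38 ± 0.45) and the signal transducer Stat4 (0.96 ± 0.13) up and Il18r1 (-2.1 ± 0.34), Il18rap (-0.76 ± 0.23), both IL-18 receptor chains, and Hopx (-1.2 ± 0.34) down. The Th1 list had adjusted p = 0.0168, but adjusted p = 0.352 with an estimated correlation. Of 27 cell cycle genes, 3 rose and 24 were not past the test, and 6 rose adjusted over the list alone. The cell cycle list had adjusted p = 0.000363, but adjusted p = 0.412 with an estimated correlation. It was not past fry either (fry adjusted p = 0.0573). The genes past the test over all genes were Plk1 (0.9 ± 0.22) and the replication licensing genes Mcm2 (0.56 ± 0.13) and Mcm5 (0.58 ± 0.15). Of 17 glycolysis genes, 7 rose and 1 fell, or 8 and 1 adjusted over the list alone, with Hif1a (1.2 ± 0.15) and the enzymes Aldoa (1 ± 0.12) and Pfkl (0.73 ± 0.13) up and Slc2a3 (-3.65 ± 0.15) down. The glycolysis list had adjusted p = 0.0227, but adjusted p = 0.198 with an estimated correlation. The glycolysis call was also lost without the second Treg library of experiment 3 (adjusted p = 0.0774) and with only the libraries not titled replicate (0.0776). Of 18 pan T cell genes, 8 rose and 2 fell, or 10 and 3 adjusted over the list alone, with Zap70 (1.7 ± 0.18), Cd4 (1.24 ± 0.14) and Cd247 (0.59 ± 0.12) up and Trat1 (-2.2 ± 0.17) and the adhesion molecule Cd2 (-0.5 ± 0.12) down. The pan T cell list had adjusted p = 0.0206, but adjusted p = 0.131 with an estimated correlation. When 1 of the 9 values was left out, calls were lost for Lag3 (adjusted p = 0.0519 without Treg of experiment 3), Mx1 (0.0512 without Treg 5), Cd2 (0.0575 without PD1hi 5) and Plk1 (0.0548 without Treg 5 and 0.0544 without PD1hi 5). In 3 of 9 cases each, the call was lost for Penk (highest 0.0636, without Treg 6), Il1r1 (0.0784, PD1hi 5), Cxcr4 (0.11, Treg 5), Cx3cr1 (0.112, Treg 6) and Mcm5 (0.0775, Treg 5). It was lost in 4 cases for Hopx (0.129, Treg 3), in 5 for Plagl1 (0.108, Treg 6) and in 7 for Ebi3 (0.15, Treg 5) and Il18rap (0.137, Treg 6). Hopx also lost its call with the experiment as a block (limma adjusted p = 0.0529).

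Lists not past the test in PD1hi against Treg included inhibitory receptors and exhaustion (9 up, 5 down of 20, adjusted over the list alone 11 and 5, camera adjusted p = 0.0511), with Ctla4 at -1.54 ± 0.14. With the experiment as a block, 13 lists passed in this comparison, among them all 12 of the main fit. A list not past the test here thus passed there, and the same held with a pseudocount of 0.5 and with no filter. Anergy genes gave 4 up and 2 down of 14 (4 and 3 adjusted over the list alone; adjusted p = 0.296), Tr1 genes 7 and 5 of 18 (the same; 0.268) with the granzyme Gzmk at 5.8 ± 0.33, and cytotoxic genes 5 and 2 of 14 (the same; 0.218) with Crtam, an adhesion receptor, at 3.14 ± 0.21. Effector and memory genes gave 9 and 8 of 25 (9 and 9 alone; 0.614), Th2 genes 1 and 3 of 9 (the same; 0.181), immediate early and stress genes 2 and 2 of 17 (the same; 0.217) and apoptosis regulators 5 and 7 of 18 (the same; 0.542). Among markers of other cell types, B cell genes gave 1 up and 5 down of 16 (the same; 0.227), with Cd22 higher in PD1hi (2.79 ± 0.23) and Cd79b higher in Treg (629.4 ± 83.8 against 129.7 ± 39.4). Plasma cell genes gave 0 of 6 (0.294), myeloid and dendritic genes 1 and 2 of 14 (0.872), and erythroid and platelet genes 0 of 5 (0.662), all the same alone. CD8 T, NK and innate-like T cell genes gave 1 and 1 of 8 (5 and 1 alone; 0.128). Signs of median, mean and test disagreed in 1 list of this comparison, effector and memory activation. Past fry but not camera were Tr1 (up, fry adjusted p = 0.00831), cytotoxic (up, 0.00802) and CD8 T, NK and innate-like T cell genes (up, 0.0467).

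Of the genes with the largest differences from Treg, Gal had no read in Treg and was at least 761-fold higher in PD1hi. The small GTPase regulator Chn1 and the peptide gene Edn3 had 3 reads in Treg (2630-fold, counting interval 900 to 12800, and 666-fold, 227 to 3240), as did Fbn2 (1600-fold, 547 to 7770), and the matrix protein Tnc had 1 (2410-fold, 432 to 95300). The vitamin D receptor Vdr rose by 8.09 ± 0.3. On the other side, the proton pump subunit Atp6v0d2 fell by 8.99 ± 0.78, Ccdc46 and Sorcs2 fell by 6.08 ± 0.59 and fell by 6.08 ± 0.64, and the retinol receptor Stra6, with 3 reads in PD1hi, was 119-fold higher in Treg (40.6 to 579). In total 2346 genes passed the limma test, 1157 higher and 1189 lower in PD1hi, 1553 of them by more than 2-fold. Of 25 lists, 12 passed with the preset correlation and 4 with an estimated one.

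**Figure D3:**
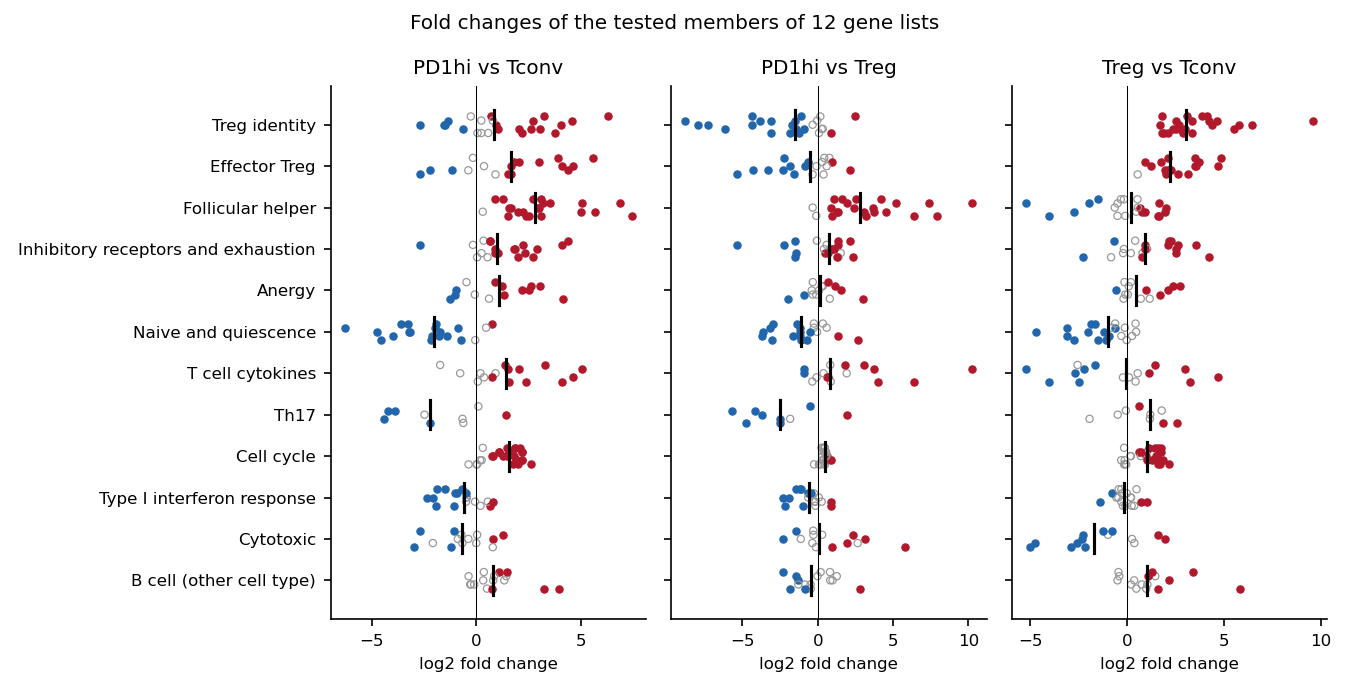
Log2 fold changes of the tested members of 12 of the 25 lists in the 3 comparisons; filled red and blue points are members higher and lower with adjusted p under 0.05, open points the others, and black bars the medians. Follicular helper genes had medians of 2.83 and 2.79 in PD1hi against Tconv and Treg and 0.18 in Treg against Tconv, and Treg identity genes had medians of 0.87, -1.5 and 3.02.

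Treg were compared with Tconv as the reference for both questions. Treg genes rose: Lrrc32 by 9.57 ± 0.34 (5687 ± 436 against 7.068 ± 3.97), Itgae by 6.43 ± 0.23, Foxp3 by 5.77 ± 0.22, Il2ra by 5.53 ± 0.13, Ikzf2 by 4.38 ± 0.14 and Ctla4 by 4.23 ± 0.14. The costimulatory receptors Tnfrsf4, Tnfrsf9 and Icos rose with them, Tnfrsf4 by 3.68 ± 0.2, Tnfrsf9 by 3.49 ± 0.15 and Icos by 2.02 ± 0.11, and so did the inhibitory receptor Tigit by 3.53 ± 0.21. Tcf7 fell by 2.74 ± 0.13, Ccr7 fell by 1.89 ± 0.13, Actn1 fell by 2.02 ± 0.15 and Dapl1, a gene of quiescent T cells, fell by 4.71 ± 0.32. Several genes of cytotoxic and Th1 cells were lower as well, the granule protein gene Nkg7 at -2.6 ± 0.24, Gzmk at -5.01 ± 0.33 and the chemokine Ccl5 at -2 ± 0.28. Other members of both lists rose or were not past the test.

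All 24 Treg identity genes rose in Treg over Tconv, also adjusted over the list alone. The Treg identity list had adjusted p = 1.66e-43, and adjusted p = 0.000313 with an estimated correlation. The list is made of genes known for Treg. Of 18 effector Treg genes, 17 rose and none fell, also adjusted over the list alone. The effector Treg list had adjusted p = 1.98e-19, and adjusted p = 0.0212 with an estimated correlation. Of 20 naive and quiescence genes, 12 fell and none rose, or 14 and 1 adjusted over the list alone. The naive list had adjusted p = 1.91e-11, and adjusted p = 0.00745 with an estimated correlation. Of 8 CD8 T, NK and innate-like T cell genes, 5 fell, or 7 adjusted over the list alone. The CD8 T list had adjusted p = 1.66e-05, and adjusted p = 0.0495 with an estimated correlation. The genes that fell included Klrb1c (141.4 ± 55.5 against 984.1 ± 59), the chemokine Xcl1 (23.21 ± 9.3 against 177.1 ± 24.3), the innate-like T cell factor Zbtb16 (18.82 ± 16.7 against 181.1 ± 67.9) and Klri2 (11.83 ± 6.64 against 62.38 ± 16.3). They moved in the direction of the lower cytotoxic and Th1 genes given below.

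The remaining lists past the test were lost with an estimated correlation. Of 14 cytotoxic genes, 9 fell and 2 rose, also adjusted over the list alone, with Crtam at -2.33 ± 0.21 and, against the list, the protease inhibitor Cst7 at 1.59 ± 0.13 and granzyme B (Gzmb) at 1.95 ± 0.38. The cytotoxic list had adjusted p = 2.62e-05, but adjusted p = 0.133 with an estimated correlation. Of 12 Th1 genes, 5 fell and 2 rose, or 8 and 2 adjusted over the list alone, with Ifng at -2.47 ± 0.36, the IL-12 receptor Il12rb2 at -2.2 ± 0.29 and Il18rap at -1.7 ± 0.23, against Cxcr3 at 0.46 ± 0.14 and Hopx at 1.21 ± 0.34. The Th1 list had adjusted p = 0.000254, but adjusted p = 0.198 with an estimated correlation. Of 27 cell cycle genes, 17 rose and none fell, or 19 and 0 adjusted over the list alone, with Mki67 at 1.72 ± 0.17, the mitosis gene Birc5 at 1.68 ± 0.29, the ribonucleotide reductase Rrm2 at 1.49 ± 0.26 and Tk1 at 1.61 ± 0.24. The cell cycle list had adjusted p = 1.05e-07, but adjusted p = 0.253 with an estimated correlation. Of 20 inhibitory receptor and exhaustion genes, 11 rose and 2 fell, also adjusted over the list alone, with the ecto-nucleotidase Entpd1 at 2.53 ± 0.19 and Cd101 at 2.15 ± 0.18, against the T-box factor Eomes at -2.28 ± 0.33 and Cd160 at -0.67 ± 0.19. The inhibitory list had adjusted p = 1.32e-05, but adjusted p = 0.0732 with an estimated correlation. Of 14 anergy genes, 5 rose and 1 fell, or 7 and 1 adjusted over the list alone, with Nrp1 at 2.74 ± 0.15, Nt5e at 2.38 ± 0.23 and Folr4 at 2.12 ± 0.14, against Dgka at -0.57 ± 0.15. The anergy list had adjusted p = 0.00146, but adjusted p = 0.131 with an estimated correlation. Nrp1, Nt5e and Folr4 are also Treg identity genes, so this call is not separate from that list. Of 9 Th2 genes, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone, with Ccr8 (3.15 ± 0.28), Il10 (4.7 ± 0.61) and Ccr4 (2.15 ± 0.34) up and Il4 (-4.01 ± 0.53) down. The Th2 list had adjusted p = 0.01, but adjusted p = 0.215 with an estimated correlation. Ccr8, Il10 and Ccr4 are also effector Treg genes.

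Of 18 Tr1 genes, 10 rose and 4 fell, also adjusted over the list alone, with Maf (1.6 ± 0.16) and Irf4 (1.74 ± 0.18) up and Gzmk, Eomes, Cd226 (-0.77 ± 0.19) and Il21 (-5.21 ± 0.36) down. The Tr1 list had adjusted p = 0.0328, but adjusted p = 0.292 with an estimated correlation. The Tr1 call was also lost with equal totals (adjusted p = 0.0565) and without the Treg value of experiment 6 (0.0515). Of 18 pan T cell genes, 4 fell and 1 rose, or 7 and 1 adjusted over the list alone, with the kinase Lck (-0.55 ± 0.13) and Cd4 (-0.71 ± 0.14) down and Cd2 (0.8 ± 0.12) up. The pan T cell list had adjusted p = 0.00198, but adjusted p = 0.0558 with an estimated correlation. Of 16 B cell genes, 6 rose and none fell, or 7 and 0 adjusted over the list alone. The B cell list had adjusted p = 0.000241, but adjusted p = 0.268 with an estimated correlation. The B cell genes that rose included Ighm (65040 ± 4000 against 21760 ± 1500), the MHC class II chaperone Cd74 (7356 ± 1200 against 2027 ± 1520), Cd79b (629.4 ± 83.8 against 57.84 ± 3.12) and Faim3 (102.7 ± 10.2 against 1.066 ± 1.07), beside Cd79a at 61.32 ± 25.3 against 29.33 ± 4.29. Of 6 plasma cell genes, 3 rose, or 4 adjusted over the list alone, with Igj at 4316 ± 1350 against 1586 ± 406 and Xbp1, a factor of secretory cells, at 0.85 ± 0.22. The plasma cell list had adjusted p = 0.00442, but adjusted p = 0.145 with an estimated correlation. Irf4, also in the Tr1 and effector Treg lists, is a member of the plasma cell list too. Lck lost its call without Tconv of experiment 6 (adjusted p = 0.0696) or without Treg 5 (0.053). In 4 of 9 such cases each the call was lost for Dgka (highest adjusted p = 0.085, without Tconv 6), Cd226 (0.0806, Tconv 3) and Xbp1 (0.097, Treg 5), and in 5 for Cxcr3 (0.198, Tconv 6), Hopx (0.137, Tconv 6) and Cd160 (0.151, Tconv 3). With the experiment as a block, Hopx lost its call as well (limma adjusted p = 0.0561).

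Follicular helper genes went both ways in Treg against Tconv (8 up, 5 down of 22, adjusted over the list alone 9 and 8; adjusted p = 0.802), with the CD40 ligand Cd40lg at -2.73 ± 0.15. Th17 genes gave 3 up and 0 down of 9 (the same adjusted over the list alone; adjusted p = 0.0732), T cell cytokines 5 and 6 of 16 (5 and 7; 0.501) and chemokine receptors 7 and 4 of 16 (the same; 0.122), with Cxcr6 at -3.62 ± 0.28. Effector and memory genes gave 9 and 5 of 25 (12 and 7; 0.172), with the IL-2 receptor chain Il2rb at 1.83 ± 0.12 and the transcriptional inhibitor Id2 at -2.24 ± 0.15. Glycolysis genes gave 3 and 3 of 17 (5 and 3; 0.904), with Slc2a3 at 1.64 ± 0.15 and Hif1a at 1.75 ± 0.15. Type I interferon response genes gave 2 and 2 of 18 (the same; 0.478), immediate early and stress genes 1 and 1 of 17 (the same; 0.39) and apoptosis regulators 3 and 2 of 18 (5 and 2; 0.179). Myeloid and dendritic genes gave 1 and 0 of 14 (0 and 0; 0.646) and erythroid and platelet genes 1 and 0 of 5 (the same; 0.215). Signs of median, mean and test disagreed in 2 lists, follicular helper and glycolysis. Past fry but not camera were Th17 (up, fry adjusted p = 0.0467), glycolysis (up, 0.0491) and apoptosis regulators (up, 0.0281).

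Among the largest rises in Treg over Tconv, Noxa1, an activator of NADPH oxidase, and Ky had no read in Tconv and were at least 181-fold and 109-fold higher, and Ccdc46 had 1 read (2480-fold, counting interval 445 to 98100). The guanylate binding protein Gbp1 rose by 7.8 ± 0.41, Glt28d2 by 6.3 ± 0.47 and the relaxin family gene Rln3 by 5.84 ± 0.45. Pdlim4 fell by 7.12 ± 0.96, Lypd6b fell by 6.78 ± 0.98, the peptidase Ggt5 fell by 5.99 ± 0.31, Nme4 fell by 5.71 ± 0.67, St6galnac1 fell by 5.7 ± 0.51, Arhgap29 fell by 5.52 ± 1.2 and Esm1 fell by 5.37 ± 0.59. In total 2039 genes passed the limma test, 1237 higher and 802 lower in Treg, 1321 of them by more than 2-fold. The genes lower in Treg numbered 498 without the Tconv value of experiment 3, 523 without that of experiment 6 and 523 without the Treg value of experiment 5. Taking the 13 libraries as separate samples gave 3151 genes. With only the 2 groups compared, 2512 genes passed here, 1896 in PD1hi against Treg and 3307 in PD1hi against Tconv. Which of Treg against Tconv and PD1hi against Treg had more genes therefore depended on the variance estimate shared by all 3 populations. Of 25 lists, 14 passed with the preset correlation and 4 with an estimated one.

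Genes that PD1hi and Treg shared against Tconv were counted last. Cd83, Ikzf2, Nrp1, Folr4, Nt5e, Itgb8, Tnfrsf4, Tigit, Icos, Maf and Irf4 rose in both, and Satb1, Ccr7, Actn1 and Pdlim4 fell in both. In all, 793 genes rose in both comparisons and 500 fell in both, where independent lists would share 175.6 and 95.49, and 151 went opposite ways (261.1 for independent lists). With 1 value left out, 553 to 945 genes rose in both and 288 to 638 fell in both. The latter numbered 288 without Tconv of experiment 3, 312 without Tconv 6 and 330 without Treg 5. Scaling to equal totals gave 907 and 395. Il21 was among the genes that went opposite ways, up in PD1hi and down in Treg, and Foxp3, Il2ra and Itgae the other way. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.478. Simulated unchanged groups that share the Tconv values gave 0.501 from noise alone, so that value does not measure the shared-control part of the observed r. The covariance of the fold changes was 0.521, against 0.0732 in the simulation. The Tconv values were also split, with experiments 3 and 5 used for PD1hi and experiment 6 for Treg, and the reverse. The covariance was 0.52 and 0.466 and r was 0.444 and 0.397, so most of r remained without shared values. The genes that rose in both then numbered 431 and 461, where independent lists would share 71.57 and 80.72, and those that fell in both 161 and 241 (22.21 and 29.77). In each split 1 comparison rests on a single Tconv value, so such counts also fall with power. Whether shared Tconv values made the deficit of genes that went opposite ways therefore cannot be told from the splits. PD1hi was higher than both other populations in 855 genes and lower in 702, Treg in 393 and 222. The root mean square log2 difference was 1.32 ± 0.17 between PD1hi and Tconv, 1.26 ± 0.11 between PD1hi and Treg and 1.03 ± 0.066 between Treg and Tconv (SD over 3 experiments). In this order it was 1.51, 1.37 and 0.97 in experiment 6 and 1.17, 1.25 and 1.1 in experiment 5. Noise adds to such a difference, and each PD1hi value is a single library while some Treg and Tconv values average 2. The larger distances of PD1hi may in part reflect this.

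**Figure D4:**
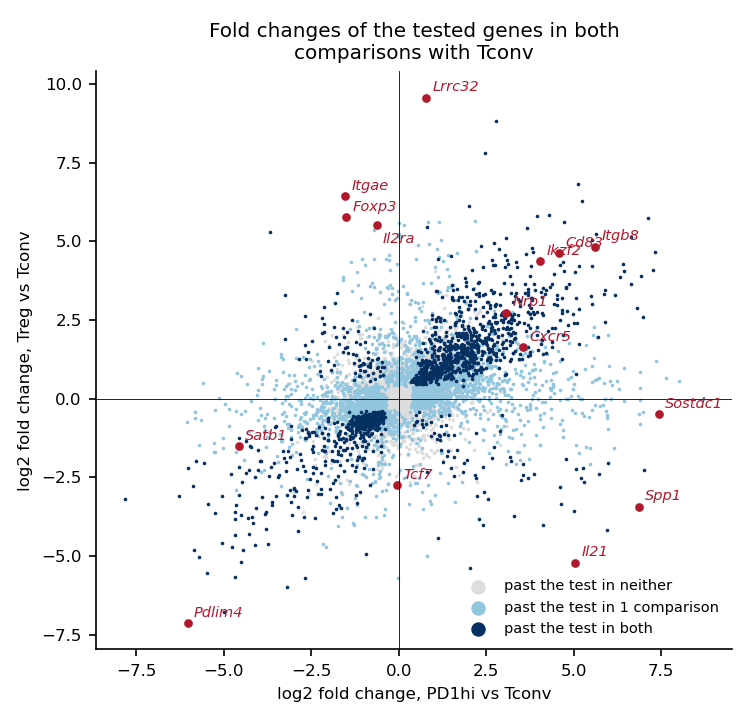
Log2 fold change of each tested gene in Treg against Tconv (vertical) over that in PD1hi against Tconv (horizontal); dark points passed the test in both comparisons, light blue points in 1, grey points in neither, and red points carry gene names. Cd83, Ikzf2 and Nrp1 lie in the upper right with 793 genes past the test in both, while Foxp3, Il2ra and Itgae lie in the upper left and Il21 in the lower right.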

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

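The tests of explanations in this part were chosen after the results were seen, except the counts of other splits of the samples, which were planned apart from the groupings that keep 1 value per experiment in each group. Measures of the libraries and the named genes printed here were compared within the Treg and the Tconv libraries, 5 each, for a library whose gap to its nearest neighbour took up over 0.71 of the group's range. The 3 PD1hi libraries are too few for that comparison. Of 323 values, 30 (9.29%) exceeded the bound, where 5 independent libraries would give about 5%. Each group holds 2 same-experiment pairs and 1 library without a partner, which can therefore stand apart more often. The named genes were also chosen from these data, so 5% is not a firm reference.

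The second Treg library of experiment 3 stood apart in 13 of these values. Its PC3 score of -50.67 lay below the other Treg libraries by 0.848 of the group's range, and its 10 most abundant genes took 8.716% of reads against 7.505 to 7.839% (0.724). Its levels were lower than in the other Treg libraries for Atp6v0d2 (2196, gap 0.826 of the range), Ccr9 (825.5, 0.713), Cd101 (982.6, 0.768), Cxcr5 (3064, 0.848), Ifit2 (1164, 0.825) and Il6st (3271, 0.748). The same held for Irf7 (1498, 0.792), Nrp1 (12090, 0.76) and Nt5e (7320, 0.818). Batf (2222, 0.869) and Tob1 (788.7, 0.775) were higher in it.

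In the Tconv library of experiment 3, the MHC class II genes H2-Aa (676.7 against 44.47 to 108.9, gap 0.898), H2-Ab1 (482.7, 0.838) and H2-Eb1 (384.7, 0.792) and the B cell gene Ms4a1 (52.22, 0.887) were above the other Tconv libraries. Cxcr4 (578.6, 0.872), Rrm2 (860, 0.795), Tbc1d4 (3259, 0.767) and the PC2 score (-32.02, 0.769) were so too. Adamts14 was high in the first Tconv library of experiment 5 (108.9, 0.841) and Il23r in the second (53.32, 0.744). In experiment 6, Cd8b1 was high in the first Tconv library (519.8, 0.73) and Crtam low in the second (226.6, 0.789). Among Treg libraries, Ms4a1 was high in the first of experiment 3 (96.43, 0.807), Lag3 (1845, 0.886) and Plagl1 (203.1, 0.798) were high in that of experiment 5, and Crtam (26.95, 0.922) and Stra6 (56.05, 0.849) were low in the second of experiment 6.

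The PD1hi library of experiment 6 and the second Treg library of experiment 3 shared an extreme PC3 score. Their deviations from the other experiments of their population correlated across genes at 0.21, with SDs of 0.883 and 0.784 log2 units against 0.555 to 0.69 in the other libraries. GC content and transcript length, known for 94.9% of tested genes, took up at most 9.21% of the variance of these deviations, against up to 16.5% in other libraries. The SDs without that trend were 0.823 and 0.733, which argues against such bias as the main source. Depth as a common source is argued against by their ranks, since the first was the shallowest and the second, of rank 13, the deepest of 13 libraries. Both libraries had the highest shares of reads in mitochondrial genes of the 13 (2.93 and 2.7%, the others 1.53 to 2.38%). Each also had the highest share in ribosomal protein genes of its population (4.3% against 3.54 and 3.78%, and 6.38% against 4.3 to 5.09%). A difference in RNA handling or in the cells sorted may remain, and these shares do not tell the 2 apart.

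Treg identity genes were raised in PD1hi cells that held little Foxp3. Treg cells sorted into the PD1hi gate by mistake could bring Treg RNA, but PD1hi held only 0.663 ± 0.194% of the Foxp3 level of Treg (SD, n = 3), while the 13 raised genes stood above Tconv by a median of 98.6% of the Treg rise in mean level (medians of 76.7 to 95.5% when taken within each experiment). The lowest of them, Capg at 17.6%, was still far above the Foxp3 share, so admixed Treg do not account for the rise of these genes. The Foxp3 share compares levels, and Foxp3 was lower in PD1hi than in Tconv. The 13 genes were picked as raised in these data. Their median therefore does not describe the whole list of 24, of which 5 fell and 6 were not past the test. No antigen-experienced population without PD-1 and Foxp3 was sorted. Whether the genes mark PD1hi cells or antigen experience in general therefore cannot be told apart here, and a biological difference of the PD1hi population stays open as an untested hypothesis.

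Ighm was higher in Treg (65040) and PD1hi (36650) than in Tconv (21760) although all were sorted as CD4 cells. B cells are argued against: within populations the log2 slope of Ighm on the B cell genes H2-Aa, H2-Ab1, H2-Eb1, Cd79a and Ms4a1 was -0.017 ± 0.036 (SE over 9 values). With all 15 tested genes of the B cell list but Ighm the slope was -0.026 ± 0.07. H2-Aa was at 150 ± 136 in Treg and 279.5 ± 345 in Tconv, Cd79a at 61.32 and 29.33 and Ms4a1 at 31.29 and 19.5. Cd79b (629.4, 129.7 and 57.84 in Treg, PD1hi and Tconv) and Cd74 (7356, 2920 and 2027) had the order of Ighm between populations, but the slopes of Ighm on them within populations were 0.0053 ± 0.14 and -0.00082 ± 0.065. What raised these genes in Treg stays open. Plasma cells as the whole source are argued against by a slope of Ighm on Igkc and Igj of 0.16 ± 0.054. Igkc itself followed Igj with a slope of 0.99 ± 0.22, consistent with RNA of plasma cells as a source of the light chain. Transcription of the Ighm locus in the T cells is a hypothesis that stays open and untested.

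The planned counts of other splits ran over the 10 ways of parting the 6 values of each comparison. The real split gave 3700, 2346 and 2039 genes in PD1hi against Tconv, PD1hi against Treg and Treg against Tconv, and the highest other split gave 0 in each, also among the 4 splits that part all 3 experiment pairs. For lists, the real splits gave 15, 12 and 14, and the highest others 11, 6 and 13; among the splits that part all 3 pairs these were 11, 3 and 13. In each of the 6 cases 1 of 10 splits, the real one, was as large, and 10 splits cannot give a share under 0.05. Of 100 random groupings of the 9 values, 1, the real one, gave as many genes changed the same way in both comparisons with Tconv (1293, highest other 998). Since the experiments pair the values, 100 of the 108 groupings that keep 1 value per experiment in each group were counted too, and 2 gave as many. These were the real one and the one that keeps the populations whole but takes PD1hi as the reference (1557), and the highest of the 97 that mix populations was 923. Only 7 of those 97 gave any gene, since mixing populations that differ widens the spread within groups. The groupings therefore show that the populations differ. They cannot tell whether the genes shared by PD1hi and Treg exceed chance, and a count as large is not particular to Tconv as the reference.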

How the results depend on the processing

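The count of changed genes in each comparison and the count shared by both comparisons with Tconv stayed within 1.5 times its main value under the alternatives set before the data were seen, with 1 exception: the 13 libraries as separate samples gave 3151 genes in Treg against Tconv instead of 2039, since 4 pairs of libraries then count as independent. Counts of a single direction moved further. That setting gave 1407 instead of 802 genes lower in Treg than in Tconv, 808 instead of 500 lower in both comparisons with Tconv and 339 instead of 222 lower in Treg than in both others. Leaving out 1 value gave as few as 498 genes lower in Treg than in Tconv and 288 lower in both comparisons with Tconv. With an estimated correlation, 5, 4 and 4 lists passed in PD1hi against Tconv, PD1hi against Treg and Treg against Tconv instead of 15, 12 and 14. In the paired fit, with the experiment as a replicate block, 3974, 2579 and 2204 genes passed, and 14, 13 and 14 lists; chemokine receptors, Iglv1, Il1r1 and Hopx lost their call there, and it ended no other call of a list or named gene. Leaving out each value in turn gave 2710 to 3833, 1764 to 2579 and 1424 to 2668 genes, 14 to 15, 12 to 13 and 13 to 16 lists, and 865 to 1583 genes shared by both comparisons with Tconv; the fewest genes came without an experiment 6 value of Tconv or Treg and the most without the PD1hi value of experiment 6. Runs chosen after the data were seen gave 3780, 2462 and 2096 genes without the second Treg library of experiment 3, 4025, 2637 and 2820 without it and the PD1hi library of experiment 6, and 3676, 2435 and 1981 with vooma weights, and duplicateCorrelation, added for the shared count, gave 1485 genes instead of 1293. Of 282 named gene results, 252 kept their side of the threshold under every alternative that tested them (a minimum mean of 50 tested 268), 30 were no longer past it under at least 1 (12 of them only when a value was left out), and 0 reversed. All 282 were past the threshold in the main fit, many picked for small adjusted p or large change, so they do not describe all calls. Of all main calls, leaving out 1 value kept as few as 72.8% in PD1hi against Tconv. The lowest shares were 73.2% in PD1hi against Treg and 69.1% in Treg against Tconv. Count-based tests on whole reads, planned with edgeR and DESeq2, were not run: the deposited table was treated as signal, and reads derived from it served for depth, read counts, folds of genes with 0 to 3 reads and sampling noise. Depth limits low genes: a gene with 1 to 3 reads in a population has a fold known only within its counting interval.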

Other observations

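Gene families named by their symbols were looked at after the data were seen, 12 families in 3 comparisons. Cytosolic ribosomal protein genes were lower in PD1hi than in Tconv in 75 of 81 cases, with a median of -0.97, and in Treg than in Tconv in 65 (median -0.64). The large subunit gene Rpl3 was at 37560 ± 3550 in PD1hi, 50120 ± 7390 in Treg and 82960 ± 7540 in Tconv, and the stalk gene Rplp0 at 28350 ± 2290, 33480 ± 5050 and 65580 ± 3190 (n = 3 each). The family passed camera at adjusted p = 6.44e-31 and 1.19e-29, and at adjusted p = 0.906 with an estimated correlation, where no family passed. Of 81 genes, 15 were lower in PD1hi than in Treg (median -0.31, adjusted p = 3.96e-08). The second Treg library of experiment 3 and the PD1hi library of experiment 6 had the highest ribosomal protein shares of their populations. Without the former 15 genes were lower in PD1hi than in Treg, with a median of -0.25, and without both 25 (median -0.31). Under TMM factors the falls numbered 75, 12 and 65 and under equal totals 73, 5 and 55 (PD1hi against Tconv, PD1hi against Treg, Treg against Tconv), with no rise. Many of these genes have processed pseudogenes that can take or give reads.

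Guanylate binding proteins, GTPases of the response to interferons, were looked at in the same way, and this family too had adjusted p = 0.906 with an estimated correlation in each comparison. Of 11 genes, 7 rose in Treg over Tconv (median 1.02, adjusted p = 7.95e-06) and 10 were lower in PD1hi than in Treg (median -1.85, adjusted p = 2.07e-12), while 8 were lower and 1, Gbp1, higher in PD1hi than in Tconv (median -0.83, adjusted p = 0.00314). Gbp7 was at 17620 ± 2100 in Treg, 7515 ± 462 in Tconv and 3435 ± 685 in PD1hi, and Gbp3 at 6559 ± 428, 1011 ± 204 and 873.2 ± 197. The directions were the same under TMM factors and equal totals. Aminoacyl-tRNA synthetases, which charge tRNA, fell in PD1hi against Tconv in 6 of 18 cases, with Iars at -1 ± 0.21 and Cars at -0.83 ± 0.16. Their camera adjusted p was 0.0265, but 0.906 with an estimated correlation, and 4 fell under equal totals. In Treg against Tconv 3 of 18 fell (camera adjusted p = 0.029), 3 under TMM factors and 0 under equal totals. Without the second Treg library of experiment 3, 1 fell there, and 4 without it and the PD1hi library of experiment 6. Complex I, cytochrome c oxidase, ATP synthase, proteasome, histone, GIMAP, schlafen, Zfp zinc finger and mitochondrially encoded genes did not pass in any of the 3 comparisons (adjusted p from 0.0701 to 0.719).

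The heat shock gene Hspa1a was lowest in experiment 6 in each population, which was not tested. It was at 1765, 1583 and 68.49 in PD1hi, 376.9, 330.1 and 15.83 in Treg and 666, 504.3 and 17.43 in Tconv in experiments 3, 5 and 6.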
